A study of Homo sapiens with 8 samples.

How the data were processed

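RNA from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, was measured on 8 Affymetrix arrays. Per the labels' protocols, 5 arrays held cells given a plasmid, an empty vector or 1 of 4 TET1 expression plasmids, and these cells were sorted by fluorescence 3 days after transfection. The other 3 arrays held cells carrying a lentiviral shRNA, with 1 control clone and 2 clones made with different shRNAs against TET1. Total RNA was extracted with Trizol, and 100 ng was amplified and biotin-labelled before hybridisation, per the labels. No label names separate cultures or a hybridisation batch.

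The deposited values are on a log2 scale, and the submitters' processing notes name Affymetrix Expression Console 1.3.1 and RMA, which corrects background, normalizes between arrays and summarises the probes of each transcript cluster. The roles and order of these tools, and the genome build, are not given in the sources used here. The table had 53981 rows, of which 364 held no value on any array, leaving 53617 transcript clusters. Array medians lay between 5.47 and 5.55 on the log2 scale. No pair of arrays held identical values. The number of arrays limits the precision of every value below.

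Gene names came from the platform annotation supplied for the series, which gave 16098 transcript clusters 1 gene symbol and none of them several. The remaining 37519 carry no name here and were tested but not named. All 16098 were found by gene number in a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and served only for names and for the order of neighbouring genes. Transcript clusters were kept where at least 2 of the 8 arrays lay above their own median. This kept 28946 clusters, 11560 of them named, for 10797 different symbols. A kept cluster may lie near or below the median on other arrays, where background may limit its value. Differences that rest on such a value may be understated, and their order is then uncertain.

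All 8 arrays entered 1 fit in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with terms for the control shRNA, the TET1 shRNAs, the empty vector, wild-type plasmid, mutant plasmid and construct (FL or CD, coded as plus or minus 0.5). The fit left 2 residual degrees of freedom. These are the difference between the 2 TET1 shRNA clones and the extent to which wild-type minus mutant differed between CD and FL, so the p-values measure that spread and not the spread of replicate cultures. The prior had 2.89 degrees of freedom and an SD of 0.154 on the log2 scale. The contrasts tested were TET1 shRNA minus control shRNA, wild-type minus mutant plasmid, the mean of the 4 TET1 plasmids minus vector, and FL minus CD. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Where each side had 1 array, differences are given without a test, and transcript clusters at least 2-fold apart were counted as a description of those arrays.

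Before the data were examined, 24 gene lists were fixed. Of these, 20 had at least 3 kept members and were tested with limma's camera, using an inter-gene correlation of 0.01 and, beside it, an estimated correlation. The version with an estimated correlation rests on the 2 residual degrees of freedom and has little power. A list that it does not call may still have shifted. A gene with several transcript clusters was represented by the one with the highest mean. The lists of replication-dependent histones, the mitochondrial genome and small nucleolar RNA had 0 named transcript clusters, and the clustered protocadherins had 1 kept member. Each list was also adjusted over its own members, called "adjusted over the list alone".

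The genes named were fixed by a rule before the data were examined. It takes TET1, the 10 highest and 10 lowest named transcript clusters per contrast among those with the same sign in each reading, and the 2 members with the largest change in each list described. It takes the 5 highest and 5 lowest where each side had 1 array. Members past the threshold over a list alone are also named, a choice made after their values were seen. Near-identical copies are named as uncertain.

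The fit was tested on simulated arrays with the design of the real ones and spreads drawn from the fitted prior, with 200 of the 28946 transcript clusters changed in each of 5 datasets per contrast. Of the 4-fold changes, 53.7% were recovered for the knockdown contrast, 76.7% for wild-type minus mutant, 66.0% for plasmids minus vector and 78.8% for FL minus CD. Of the 2-fold changes, the shares were 0%, 4.18%, 1.79% and 3.28%. Of the 16-fold changes, they were 91.2%, 98.5%, 95.2% and 97.3%. Unchanged clusters were called wrongly 5.8, 7, 6.2 and 6.4 times per dataset on average. Drawing from the prior was chosen after spreads taken from the fitted posterior had given more false calls. That version gave 10.8, 19.2, 19 and 17.8 false calls and recovered 94.9%, 99.4%, 98.5% and 99.7% of the 4-fold changes. Both versions gave all arrays 1 spread per cluster and planted the 3 sizes of change in near-equal numbers. Neither need hold for the real arrays, so the recovered shares may be too high. In the real fit TET1 16715048, 61.2- to 75.4-fold above the vector, did not pass. Unchanged arrays sharing 1 control were simulated 100 times with the fitted spread, pooled over all arrays. This gave the overlap that a shared control of that spread makes with no effect. Random lists matched on mean level numbered 10000 per list.

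Alternatives were other filters, array centring, cyclic loess, a trend or robust prior, 1 transcript cluster per symbol, fewer arrays in the fit, each shRNA clone or plasmid array left out, a looser threshold of 0.1, and an estimated correlation for the lists. Added after the data were seen were the empty vector or the mean of both controls in place of the control shRNA array, each clone set against each construct, lists with arrays left out, the ZNF medians between arrays other than the control clone, an estimated correlation for lists against the vector and for lists that passed only in another setting, another definition of clustered ZNF genes, and p53 targets against each shRNA array. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.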

Results

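Expression was profiled in HEK293T cells given shRNA against TET1 or a plasmid that supplies it. TET1 is a dioxygenase that oxidises 5-methylcytosine in DNA, and the design set wild-type against catalytically mutant protein in the constructs labelled CD and FL. There was 1 array each for the control shRNA, the empty vector and each of the 4 TET1 plasmids (wild-type TET1-CD and TET1-FL, mutant mTET1-CD and mTET1-FL), and 2 arrays for TET1 shRNA, 1 per clone. Across the 28946 transcript clusters kept, the arrays correlated in pairs with r between 0.932 and 0.988. The highest values were those of TET1-CD with mTET1-CD (0.988) and TET1-FL with mTET1-FL (0.985). The first principal component held 38.3% of the variance and placed the 3 shRNA arrays, at -39.8 to -33.9, below the 5 plasmid and vector arrays, at 4.94 to 40.9.

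TET1 itself was measured by 2 transcript clusters. The first, 16705381, stood at 9.29 in the control clone, 8.62 in shTET1#1 and 9.14 in shTET1#2 on the log2 scale. Signal in shTET1#1 was thus 1.59-fold lower than in the control, and in shTET1#2 it was 1.11-fold lower. The second, 16715048, stood at 5.71 in the control, 5.27 in shTET1#1 and 6.20 in shTET1#2, differences of -0.44 and 0.49. Which part of the transcript each cluster reads was not analysed here. These shRNA values of 16715048 lay near the array medians of 5.47 to 5.55, where background may limit the reading. Because 16705381 was only 1.11-fold lower in the second clone and 16715048 gave no lower value there, that sample is called the array labelled shTET1#2. The fitted knockdown differences were -0.41 ± 0.27 (SE) and 0.024 ± 0.40, and neither passed the threshold (limma adjusted p = 0.782 and 0.997).

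Plasmid cells had far more TET1 signal. Cluster 16715048 stood at 5.86 with the vector, 12.10 and 12.03 with wild-type and mutant CD, and 11.80 and 11.91 with wild-type and mutant FL, which is 75.4-, 71.8-, 61.2- and 66.1-fold above the vector. That vector value lay near the array median of 5.52, where background may hold it up, so these folds are best read as lower bounds. Cluster 16705381 stood at 9.51 with the vector, 10.42 and 11.05 with wild-type and mutant CD, and 12.22 and 12.47 with wild-type and mutant FL. Wild-type and mutant plasmids of the same construct differed by 0.071 (CD) and -0.11 (FL) in 16715048, and by -0.63 and -0.25 in 16705381.

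**Figure D1:**
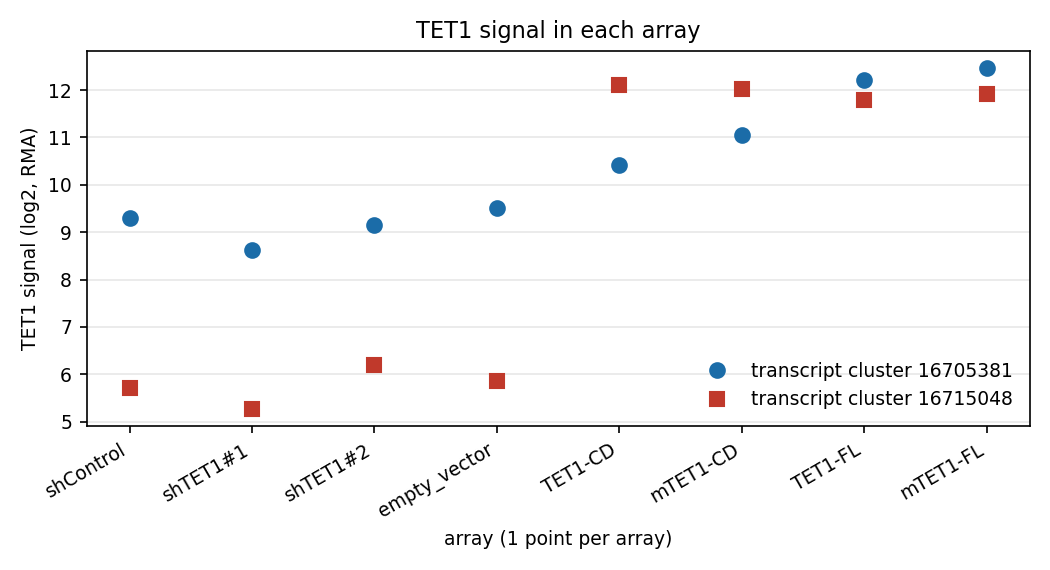
TET1 signal on the log2 scale (y axis) in each of the 8 arrays (x axis), with 1 point per array for each of the 2 transcript clusters. The shTET1#2 points lie close to or above the control shRNA points, and all 4 plasmid arrays lie above the vector in both clusters.

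The first comparison set the 2 clones with shRNA against TET1, of which the array labelled shTET1#2 had little or no lower TET1 signal, against the control clone. Among named transcript clusters, SNAI2, a transcription factor of mesenchymal transition, had the largest excess over the control clone in both clones. It stood at 3.95 ± 0.51 (SE, log2), with 4.56 in shTET1#1 and 3.33 in the array labelled shTET1#2. MAP7D2 was higher by 3.45, the cancer-testis gene SAGE1 by 3.01, LINC00665 by 2.84 and the TNF receptor family gene EDA2R by 2.67. LOC100507412 (2.43), the zinc finger genes ZNF527 (2.33), ZNF681 (2.28) and ZNF83 (2.01), and CPPED1 (2.08) followed. On the lower side stood GFRA3, a co-receptor for the neurotrophic factor artemin, at -3.41 ± 0.22, then LYPD4 (-2.99), the long noncoding RNA PURPL (-2.44), the ketone-body enzyme OXCT1 (-2.36) and the synaptic vesicle protein gene SV2A (-2.03). ACSS3 (-1.76), FENDRR (-1.68), COLEC12 (-1.50), MNS1 (-1.47) and the intermediate filament gene VIM (-1.38) completed the 10 lowest. MNS1 differed by -2.49 in shTET1#1 and by -0.46 in the other clone.

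None of the 28946 clusters passed the limma threshold for knockdown, the lowest adjusted p being 0.16, and 2294 (7.93%) had an unadjusted p under 0.05. With 1 transcript cluster per gene symbol, no unnamed clusters and the prior refitted, 5 genes passed, namely SAGE1, LINC00665 and CPPED1, which were higher, and GFRA3 and LYPD4, which were lower (adjusted p = 0.0139 to 0.0186 in that setting). A 2-fold excess in both clones was seen for 125 clusters and a 2-fold deficit for 111, against 18.95 and 19.65 with simulated unchanged arrays that share 1 control and 3.53 and 5.67 for independent lists. The simulation gave all arrays 1 spread per cluster, pooled over the clones and the wild-type and mutant pairs. The clones were further apart (SD of their difference 0.394) than wild-type and mutant in CD (0.241) or FL (0.269). The simulated counts may thus be too low, and the pooled spread may make the knockdown p-values too small. Only 1 control array exists, so how much of the excess comes from sharing it cannot be told. The clones' differences correlated at r = 0.517 across transcript clusters, against 0.499 in simulation, and their covariance was 0.0800 against 0.0365.

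The empty vector array, which carries no shRNA, was set beside these genes. Its cells were given a plasmid and sorted 3 days later, whereas the clones carried a lentiviral shRNA. Differences between the vector array and the shRNA arrays, here and below, thus cannot be assigned to the shRNA alone. For SNAI2 it stood 4.21 above the control clone, for MAP7D2 2.93 and for ZNF527 2.44. Of the 125 clusters higher in both clones, 103 (82.4%) had a vector value nearer the clones than the control clone, and the vector made up a median 82.8% of the shift. Such clusters are chosen against the same control array, so simulated unchanged arrays gave 64.9% and 67.1%. Of the 111 lower clusters, 61 (55.0%) did, at a median of 54.1%, below the simulated 65.8% and 66.3%. PURPL and ACSS3 were different, the vector standing 0.36 and -0.0092 from the control clone. Against the vector in place of the control clone, all of the 10 lowest genes and 6 of the 10 highest kept their sign. These genes were picked as extremes of the same clone arrays, so kept signs are partly expected without an effect. No simulated count of signs was made. PURPL stood at -2.81, ACSS3 at -1.75, GFRA3 at -1.50, EDA2R at 0.77, CPPED1 at 0.73 and SAGE1 at 0.70. SNAI2 was -0.27, LOC100507412 -0.27, ZNF527 -0.12 and ZNF83 -0.053 in the same comparison, and limma called 0 clusters, with 4395 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0894.

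**Figure D2:**
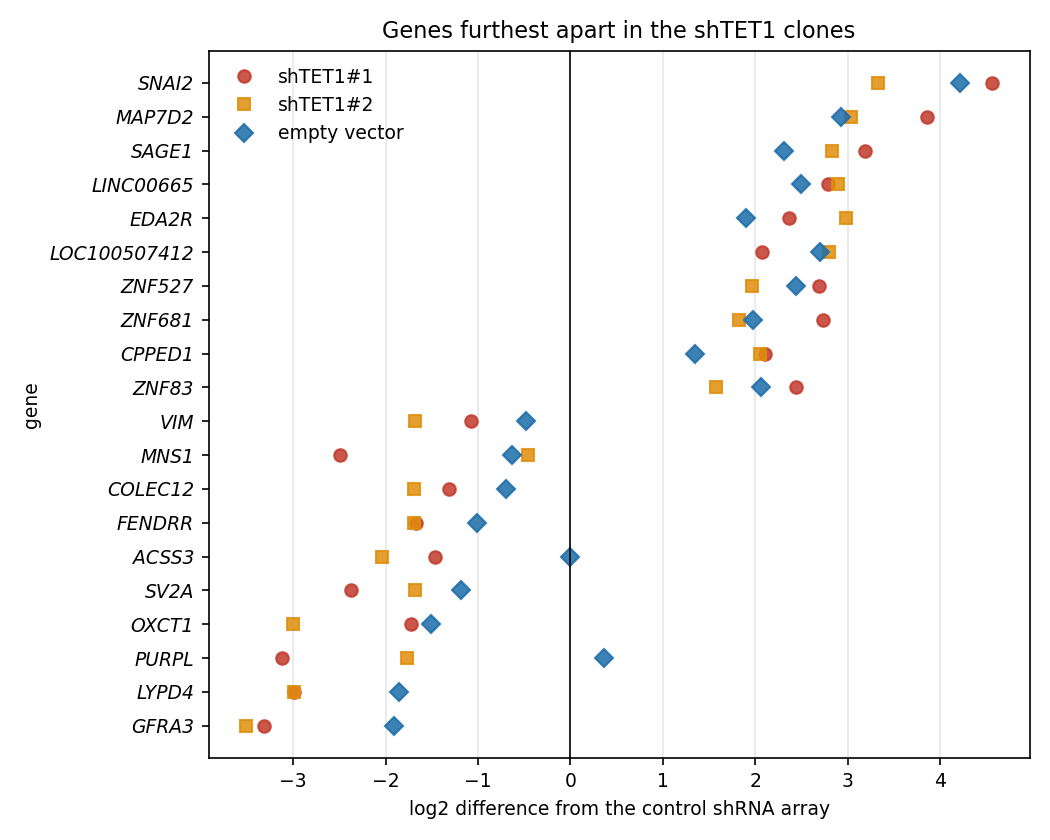
Log2 difference from the control shRNA array (x axis) for the 10 highest and 10 lowest named genes (y axis) in shTET1#1, in the array labelled shTET1#2 and in the empty vector array, 1 point per array. For the 10 highest genes the vector points lie between 1.34 (CPPED1) and 4.21 (SNAI2), below both shRNA clones for MAP7D2, SAGE1, LINC00665, EDA2R and CPPED1, and for PURPL and ACSS3 they lie near 0.

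Among the gene lists, HOX genes, homeobox regulators of body axis, had a fitted difference below 0 between the TET1 shRNA clones and the control in 24 of 26 members, with a median of -0.27. The camera adjusted p was 8.5e-04 with the preset correlation, but adjusted p = 0.774 with an estimated correlation. Its median was -0.41 in shTET1#1, where random lists matched on mean level had 0.017. In the array labelled shTET1#2 it was -0.083, against -0.081 for matched lists (percentile 48.0). HOXB6 stood at -0.73 and HOXB5 at -0.64. Against the vector the HOX median was -0.046, and HOXB6 and HOXB5 stood at 0.13 and 0.035. Genes commonly methylated in cancer had a median of -0.077, with 21 of 33 lower (adjusted p = 0.0416, and adjusted p = 0.774 with an estimated correlation), among them TFPI2 at -0.94 and the Wnt antagonist SFRP1 at -0.83. Ribosomal protein genes were lower in 24 of 33, with a median of -0.14 (adjusted p = 0.0416, and adjusted p = 0.774 with an estimated correlation), including RPL32 at -0.50 and RPS23 at -0.41. In the array labelled shTET1#2 the ribosomal median of -0.098 lay at percentile 41.9 of matched lists, whose median was -0.090. Over its own members alone the p53 list gave EDA2R at 2.67 and the kinase gene PLK2 at -0.82 (0.00565 and 0.0338 adjusted over the list alone), while the list's median was -0.18 and its camera adjusted p was 0.224. Without shTET1#1 the HOX, cancer-methylated and ribosomal medians were -0.083, -0.21 and -0.098 and none passed (camera adjusted p = 0.352, 0.172 and 0.483), and without the array labelled shTET1#2 the cancer-methylated median was -0.030 (0.127). The unfolded protein and amino-acid list passed without shTET1#1 (median -0.21, adjusted p = 0.05, and adjusted p = 0.81 with an estimated correlation) but had a median of 0.10 in shTET1#1 alone, and cholesterol synthesis passed without the array labelled shTET1#2 (0.17, adjusted p = 0.0407, and adjusted p = 0.852 with an estimated correlation). With cyclic loess the cancer-methylated and ribosomal lists did not pass (camera adjusted p = 0.0739 and 0.116). Without the filter on low signal the cancer-methylated list did not pass (0.176). Against the vector the ribosomal and cancer-methylated lists did not pass (0.532 and 0.349), while the unfolded protein and amino-acid list (-0.29) and the hypoxia and glycolysis list (-0.27) did, both at 0.00219 with the preset correlation (adjusted p = 0.945 for both with an estimated correlation). The other lists had adjusted p between 0.152 and 0.969, and median and mean differed in sign for germline, immediate early, epithelial, neuronal and blood cell genes.

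In single clones, 315 clusters were at least 2-fold higher and 262 at least 2-fold lower in shTET1#1 than in the control, and 324 and 626 in the array labelled shTET1#2. Without the filter on low signal the share of higher clusters among those 2-fold apart in shTET1#1 was 49.4% in place of 54.6%. Centring each array on its median moved the share of higher clusters among those 2-fold apart in the second from 34.1% to 24.1%, and its overall median to -0.12. Beyond genes named above, AMBN stood at 2.86 in shTET1#1 and TSSC2 at -1.93 in the array labelled shTET1#2. The 2 clones themselves were 2-fold apart in 463 and 220 clusters, and the vector and control shRNA arrays in 604 and 711.

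The second comparison, wild-type minus mutant, asked what depends on the catalytic activity of the supplied TET1. TCEAL7 was the only named gene 2-fold apart in the same direction in both constructs, at 1.05 with CD and 1.18 with FL (1.12 ± 0.16, limma adjusted p = 1). Next on the higher side were LINC02525 (0.73), ZNF585B (0.71), LCMT1P1 (0.68), TPH1, which makes serotonin's precursor (0.67), NAGS (0.67), ZNF157 (0.61), ZNF750 (0.60), ZNF10 (0.60) and LOC100130673 (0.59). Lowest were MIR4526 (-0.81), NPAP1P9 (-0.66), MIR1269A (-0.66), MIR4518 (-0.66), the transcription factor OVOL2 (-0.63), the pore-forming gene GSDMD (-0.63), MIR4262 (-0.60), MIR501 (-0.59), KRTAP10-1 (-0.59) and TEX44 (-0.54). None of the 28946 clusters passed (limma, lowest adjusted p = 1), and 567 (1.96%) had an unadjusted p under 0.05. The spread used includes the difference between the 2 shRNA clones, which was larger (SD 0.394) than wild-type minus mutant in CD (0.241) or FL (0.269). These p-values may thus be too large. With the 5 plasmid and vector arrays alone, 1458 clusters had an unadjusted limma p under 0.05 and 0 passed.

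TET1-CD minus mTET1-CD was 2-fold higher in 93 clusters and lower in 70, and TET1-FL minus mTET1-FL in 73 and 140. Without the filter on low signal the share of higher clusters moved from 34.3% to 54.4% for FL, and from 57.1% to 56.7% for CD. With the filter, 27 clusters were 2-fold apart in both constructs, against 1.2 for independent lists. Of these, 20 had opposite directions (0.626 for independent lists) and 7 the same direction (3 higher and 4 lower, against 0.235 and 0.339). Across transcript clusters, which are not independent replicates, the differences correlated at r = 0.0042 and rho = 0.031. ULBP1 (0.96), TKTL1 (0.89) and CCDC30 (0.86) stood out with CD, as did TMEM229A (-0.89), MSX2P1 (-0.87) and KRTAP3-2 (-0.81). With FL they were VTRNA1-2 (1.08), MSX2P1 (0.95), MIR3194 (0.93), HNRNPA1P33 (-1.41), MIR378E (-1.06), MIR191 (-1.02) and SIAE (-1.004), MSX2P1 thus having opposite signs in the 2 constructs.

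**Figure D3:**
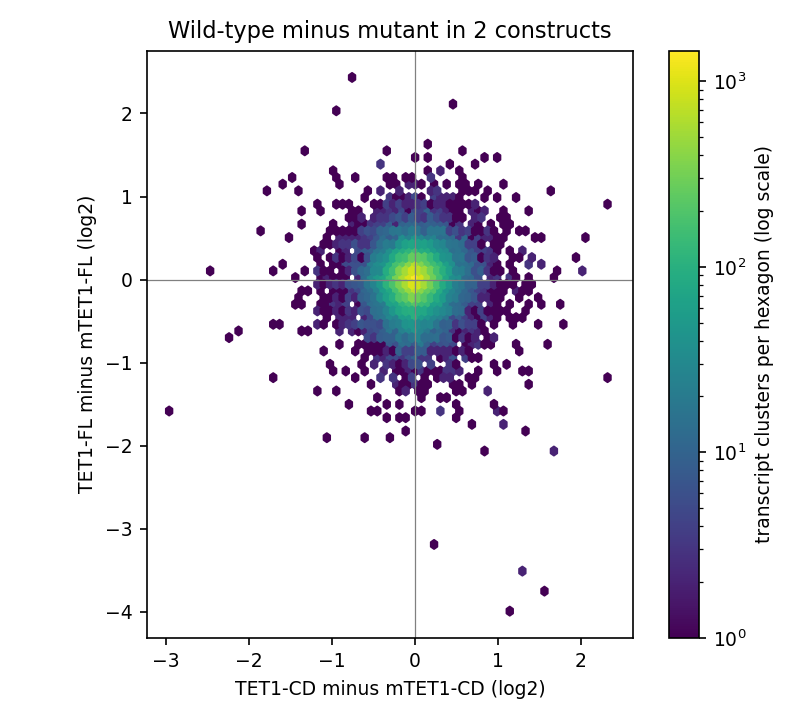
Wild-type minus mutant on the log2 scale in the CD construct (x axis) and the FL construct (y axis) for the 28946 transcript clusters, coloured by the number per hexagon on a log scale. The cloud is centred on 0 and has no visible slope (r = 0.0042).

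Ribosomal protein genes were lower with the wild-type proteins in 29 of 33 members, with a median of -0.084, and epithelial genes were higher in 12 of 15, with a median of 0.13. Both had a camera adjusted p of 0.0383, and adjusted p = 0.973 with an estimated correlation. RPL31 stood at -0.47 and RPS27 at -0.30, and the epithelial genes EPCAM and KRT8 at 0.46 and 0.32. Without the CD arrays the medians were -0.026 and 0.11 and neither passed (0.66 and 0.657), and without the FL arrays they were -0.12 and 0.074 and epithelial genes did not pass (0.0288 and 0.0522). Neither passed with cyclic loess (0.0665 and 0.0573) or without the filter on low signal (0.182 and 0.229). Their medians were -0.059 and 0.13 with cyclic loess and -0.084 and 0.067 without the filter. Germline and cancer-testis genes, many of them silenced by methylation in somatic cells, had a median of 0.51 with CD and 0.081 with FL over 6 members (0.27 in the fit, adjusted p = 0.457), and imprinted genes were lower in 8 of 17 (adjusted p = 0.841). The p53 targets had a median of 0.11 (adjusted p = 0.0773). Median and mean differed in sign for HOX genes and for the unfolded protein and amino-acid list.

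Knockdown and catalytic differences share no array and were set against each other across transcript clusters, which are not independent replicates. The correlation was r = -0.121 and rho = -0.138. Clone by construct it was 0.063 for shTET1#1 with CD, -0.032 for shTET1#1 with FL, -0.036 for the array labelled shTET1#2 with CD and -0.246 for it with FL. The pooled value thus came mostly from 1 of the 4 pairs.

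The third comparison set the 4 TET1 plasmids against the empty vector. After TET1, the highest were ZNF224 (1.96 ± 0.33), PIH1D2 (1.86), the small RNA gene SNAR-H (1.66, a family of near-identical copies and so uncertain), KIAA0825 (1.66) and PLK2 (1.65 ± 0.14). RPL23AP82, in 2 transcript clusters, and RPL23AP87 all stood at 1.63 with identical array values, and these pseudogene copies cannot be separated. The lowest were the dopamine receptor gene DRD4 (-1.39 ± 0.18), DPRXP4 (-1.17), ZFP14 (-1.05), the collagen cross-linking gene LOXL2 (-1.02), ASS1, an enzyme of arginine synthesis (-1.01), GAS5-AS1 (-0.998), MIR222 (-0.98), LPCAT4 (-0.96), MIR548I2 (-0.96) and DLEU2L (-0.95). None passed, TET1 included (limma, lowest adjusted p = 0.162), and 4352 clusters (15.0%) had an unadjusted p under 0.05. Centring each array on its median brought 1 cluster past, TET1 16715048 (adjusted p = 0.0477). All 4 plasmids were at least 2-fold above the vector in 160 clusters and below it in 16, against 4.95 and 5.11 in simulated unchanged arrays that share 1 control. The vector had 1 array, so its own deviation enters each of the 4 differences.

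Targets of p53, the tumour suppressor that large T antigen binds in these cells, were higher with the plasmids in 16 of 20 members. Their median was 0.60, and by plasmid it was 0.65 and 0.44 with wild-type and mutant CD and 0.77 and 0.73 with wild-type and mutant FL. The camera adjusted p was 3.18e-07, and adjusted p = 0.506 with an estimated correlation. Adjusted over the list alone, 9 genes passed (over all clusters, 0): PLK2 (1.65), the cytokine gene GDF15 (1.29), AEN (1.12), RRM2B (1.03), PLK3 (0.84), the apoptosis effector gene BAX (0.76), SESN1 (0.73), TRIAP1 (0.57) and TIGAR (0.52). Against the 3 shRNA arrays, a comparison chosen after this shift was seen, the median of the 4 plasmids was higher by 0.46 (control shRNA), 0.57 (shTET1#1) and 0.70 (array labelled shTET1#2). Their 95% bootstrap intervals over genes were 0.29 to 0.74, 0.36 to 0.96 and 0.48 to 0.81. The plasmid cells were transfected and sorted and the shRNA cells carried a lentivirus, so these values cannot be told apart from that difference.

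Cell-cycle genes were higher with the plasmids in 35 of 48 members, with a median of 0.29 (camera adjusted p = 1.32e-05, and adjusted p = 0.728 with an estimated correlation). The mitotic genes HMMR (1.27) and CDC20 (1.02) passed adjusted over the list alone. Lower lists were the unfolded protein and amino-acid response (15 of 21 lower, median -0.29, adjusted p = 0.0237, and adjusted p = 0.802 with an estimated correlation), with DDIT4 at -0.79 and ASNS at -0.78, and cholesterol synthesis (12 of 17, median -0.17, adjusted p = 0.0476, and adjusted p = 0.728 with an estimated correlation), with INSIG1 at -0.84 and HMGCS1 at -0.74. Hypoxia and glycolysis genes were lower in 17 of 21, with a median of -0.12 (adjusted p = 0.0476, and adjusted p = 0.802 with an estimated correlation), DDIT4 again and NDRG1 (-0.54) being furthest. By plasmid its median was -0.35 and -0.22 with wild-type and mutant CD, but 0.019 and -0.021 with wild-type and mutant FL (percentiles 63 and 45.1 of matched lists). In the same order the unfolded protein medians were -0.31, -0.28, -0.078 and -0.13, and those of cholesterol synthesis -0.32, -0.46, -0.16 and -0.14. Extracellular matrix genes, fixed as fibroblast markers, were lower in 6 of 7, with a median of -0.36 (adjusted p = 0.0237, and adjusted p = 0.728 with an estimated correlation), with LOXL2 at -1.02 and FN1 at -0.84. FN1 stood at 8.89 in the vector array, 7.69 to 8.44 in the plasmid arrays and 7.24 to 7.46 in the shRNA arrays, and INSIG1 at 10.8, 9.60 to 10.3 and 9.42 to 9.87. With 1 plasmid array left out, the construct term makes the fitted plasmid mean rest on 2 of the 4 arrays. Resting on mTET1-CD and TET1-FL (without TET1-CD or mTET1-FL, the same value), these 4 lower lists did not pass, at medians of -0.25, -0.14, -0.099 and -0.38 (camera adjusted p = 0.0634, 0.0967, 0.112 and 0.0634). Resting on TET1-CD and mTET1-FL, cholesterol synthesis did not (-0.21, 0.0551). Without the filter on low signal they did not pass either (0.058, 0.103, 0.103 and 0.223), the extracellular matrix median moving to -0.20 and the other 3 staying as they were. In that setting the immediate early list passed, at a median of 0.083 (adjusted p = 0.0477, and adjusted p = 0.614 with an estimated correlation). Adjusted over the list alone, the methylation machinery gave TET1 (2.03), the germline list TEX14 (1.04) and CTAG2 (-0.51), and the inflammatory list LIF (1.12), with NEIL1 at -0.60, PIWIL4 at 0.68 and NFKB1 at 0.61 beside them. The median of the interferon list, whose genes respond to foreign nucleic acid, was 0.075 (adjusted p = 0.495).

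By single plasmid, 718 clusters were 2-fold higher and 348 lower with TET1-CD, 500 and 408 with mTET1-CD, 897 and 146 with TET1-FL, and 761 and 115 with mTET1-FL. Without the filter on low signal the share of higher clusters moved from 67.4% to 54.2% with TET1-CD, from 55.1% to 43.4% with mTET1-CD, from 86.0% to 72.7% with TET1-FL and from 86.9% to 67.1% with mTET1-FL. CFAP43 (2.13) was among the highest with TET1-CD and USP17L12, one of many near-identical copies and so uncertain, with TET1-FL (2.14) and mTET1-FL (2.03). Among the lowest were SCARNA22 (-1.57), STC1 (-1.40), MIR218-1 (-1.35) and ARRDC4 (-1.32) with TET1-CD, STC1 (-1.59) with mTET1-CD, S100A6 (-1.15) and TLL2 (-1.10) with TET1-FL, and SIGLEC7 (-1.26) and AQP12A (-1.14) with mTET1-FL.

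The fourth comparison set FL against CD. Highest with FL were MIR554 (1.77 ± 0.42), ANKRD1, a stress-responsive muscle ankyrin repeat gene (1.73 ± 0.13), TET1 16705381 (1.61 ± 0.22), SCARNA22 (1.59), COX6A1 of the respiratory chain (1.53), MIR15B (1.49), USP17L15 (1.47, also of the USP17L copies), STC1 (1.47), LOC100272217 (1.44) and MIR3143 (1.34). The other TET1 cluster, 16715048, went the opposite way, at -0.30 in the wild-type pair and -0.12 in the mutant pair. Lowest were the intestinal enzyme gene MGAM (-1.34 ± 0.12), DRC11 (-1.26), MIR570 (-1.10), KIAA0825 (-1.09), CEP192P1 (-1.03), ANKRD31 (-0.95), C2orf66 (-0.94), DRP2 (-0.92), ENO4 (-0.91) and POLN (-0.89). None passed (limma, lowest adjusted p = 0.114), and 3975 clusters (13.7%) had an unadjusted p under 0.05. Both pairs were 2-fold higher with FL in 298 clusters and lower in 26. Of the 298, 282 (94.6%) carry no gene name here, against 60.1% of all kept clusters.

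All 33 ribosomal protein genes were higher with FL, with a median of 0.35 (camera adjusted p = 8.74e-09, and adjusted p = 0.771 with an estimated correlation), RPL32 standing at 0.87 and RPL34 at 0.74. Immediate early genes, which respond to serum and stress, were higher in 21 of 24, with a median of 0.43 (adjusted p = 2.51e-06, and adjusted p = 0.759 with an estimated correlation). FOS stood at 0.82 and DUSP5 at 0.77, and KLF10 (0.76), IER2 (0.74), JUNB (0.73), CCN2 (0.68) and KLF2 (0.57) passed adjusted over the list alone. Hypoxia and glycolysis genes were higher in 19 of 21, with a median of 0.25 (adjusted p = 2.41e-04, and adjusted p = 0.759 with an estimated correlation), including ADM at 0.65 and ANKRD37 at 0.65. The p53 targets were higher in 15 of 20, with a median of 0.27 (adjusted p = 0.00559, and adjusted p = 0.759 with an estimated correlation), and PLK2 (1.3), GDF15 (0.87), TRIAP1 (0.68) and BBC3 (0.58) passed adjusted over the list alone. Without the mutant arrays the p53 median was 0.18 and the list did not pass (0.0592). Also past, adjusted over the list alone, were TET1 (1.61, by cluster 16705381 only), IER3 (0.73), FN1 (0.73) and the macrophage marker CD68 (0.99), beside which UHRF1 stood at -0.49, NFKB1 at -0.44, THY1 at 0.19 and LAPTM5 at -0.16. The blood cell list as a whole had a median of -0.12 but a mean of 0.15 over 4 members (adjusted p = 0.972), and epithelial genes also had a median and a mean of different sign.

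**Figure D4:**
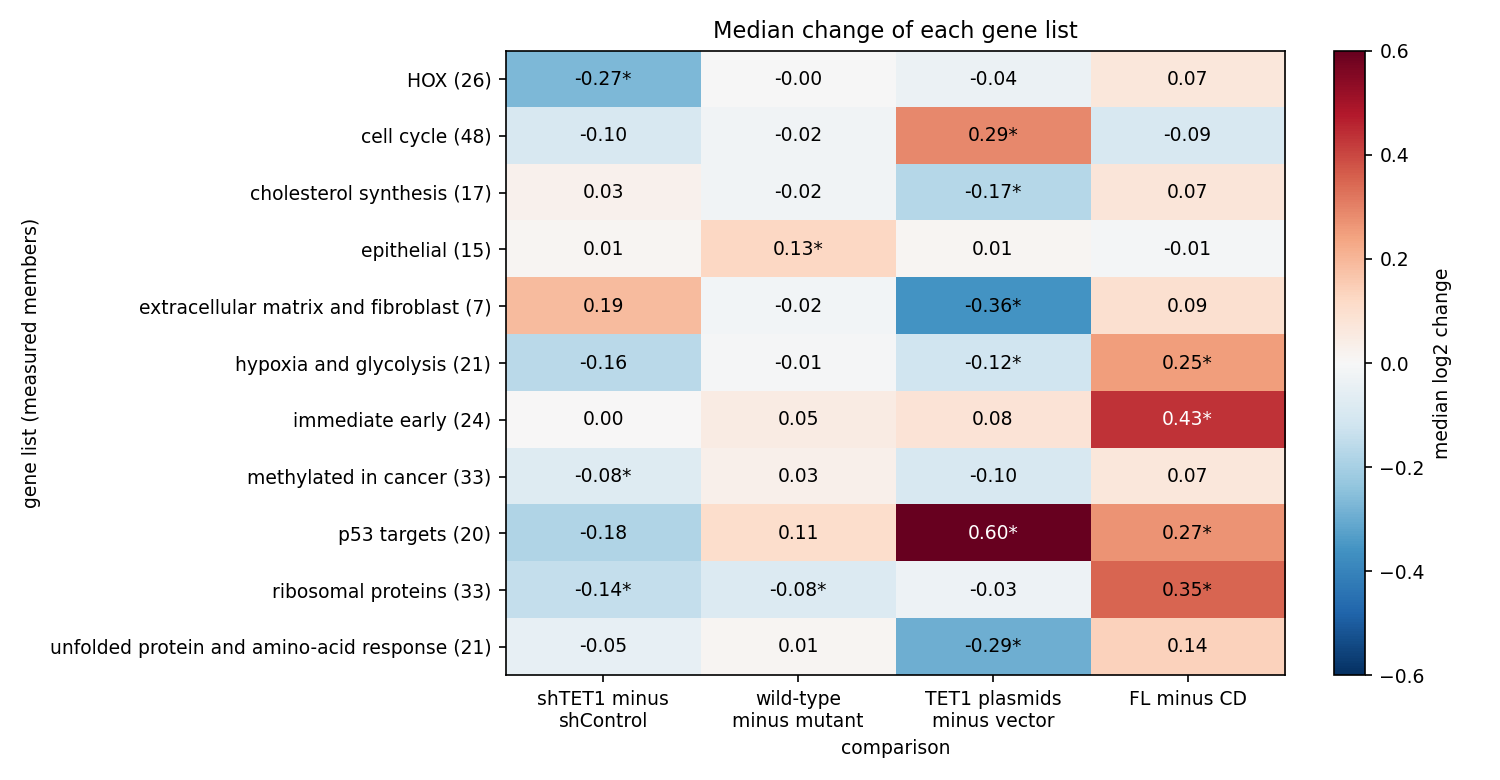
Median log2 change (colour and printed value) of each gene list (rows, measured members in brackets) in the 4 comparisons (columns), for lists past the camera threshold in at least 1 comparison; an asterisk marks an adjusted p under 0.05 with the preset correlation. The p53 targets at 0.60 with TET1 plasmids are the strongest colour. No asterisk holds with an estimated correlation, a version with little power at 2 residual degrees of freedom.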

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

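Gene lists were looked at again where the change against the vector differed between the FL and CD plasmids by the test of that difference itself, and none of these tests was chosen only after the result was seen. The difference, FL minus CD, had a median of 0.27 for p53 targets, 0.43 for immediate early genes, 0.25 for hypoxia and glycolysis genes and 0.35 for ribosomal protein genes. Against the vector, ribosomal protein medians were -0.22 and -0.12 with wild-type and mutant CD, and 0.10 and 0.14 with wild-type and mutant FL. Immediate early medians were -0.065, -0.033, 0.42 and 0.23 in the same order, and those of hypoxia and glycolysis genes -0.35, -0.22, 0.019 and -0.021. Each call was made with the preset correlation only, with adjusted p = 0.759 to 0.771 with an estimated correlation. No group held enough arrays for a search for outlying samples.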

How the results depend on the processing

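The settings with the vector or both controls, the lists with arrays left out (CD or FL included) and the clone by construct pairs were chosen after seeing the data, and the others were planned. Of 1378 values of named genes recomputed, 1358 kept their direction and their side of the threshold. Another 6 moved past the threshold and 14 changed sign. The cause was not tested except where stated. The 1358 is no measure of stability, since many of these values could not move. Other filters, a trend or robust prior and 1 transcript cluster per symbol left fitted differences unchanged, so signs were fixed there. The highest and lowest genes were chosen for the same sign in each reading, so leaving out a clone or construct could not reverse them. No gene passed in the main fit, so none could fall back. Counts past the limma threshold moved from 0 to 5 for knockdown with 1 transcript cluster per symbol, where unnamed clusters were left out and the prior was refitted at once, and to 1 for plasmids against vector when centred. They stayed at 0 in every other setting, including without each clone or plasmid array and at a threshold of 0.1. Fits without a clone or plasmid array assume that a lone array varies like the others. TET1 16715048 in the knockdown stood at -0.023 when centred, from -0.44 to 0.49 without a clone, -0.13 against the vector and -0.052 against both controls. Its catalytic value was 0.071 without the FL arrays, and LAPTM5 for FL minus CD was 0.065 without the wild-type arrays. Against the vector the knockdown values were -0.27 for SNAI2, -0.27 for LOC100507412, -0.12 for ZNF527, -0.053 for ZNF83, 0.13 for HOXB6, 0.035 for HOXB5, 0.25 for RPL32 and 0.044 for RPS23, and the HOX list, with a median of -0.046, changed its direction in the test. The number of lists past the threshold became 0 in all 4 comparisons with an estimated correlation. That setting rests on 2 residual degrees of freedom, and its lowest unadjusted camera p was 0.0253 (p53 targets, plasmids against vector). It could thus call few lists, and the 0 does not decide between the 2 settings. With cyclic loess the number was 1 for knockdown and 0 for catalytic, and without the filter 0 for catalytic and 3 for plasmids against vector. It ranged from 1 to 3 for knockdown without a clone and from 2 to 5 for plasmids against vector without a plasmid array (fits whose plasmid mean rests on 2 arrays), and for catalytic was 0 without the CD arrays and 1 without the FL arrays. At 1.5-fold, the clusters apart numbered 2315 and 3926 for the shRNA clones, 867 and 1244 for CD and FL wild-type minus mutant, and 4549 and 3886 for wild-type and mutant CD and 3762 and 3459 for wild-type and mutant FL against vector. Without the filter on low signal, the clusters at least 2-fold apart numbered 1300, 1877, 494, 789, 1937, 1746, 1938 and 1653 in the same order. The higher share for FL wild-type minus mutant then moved from 34.3% to 54.4%. CD and FL correlated at 0.019 with the filter on the mean. Knockdown with catalytic was -0.099 without the filter, ranged from -0.207 to 0.018 without a clone, and by pair was 0.063, -0.032, -0.036 and -0.246. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers; this concerns replicate numbers only, since the construct term sets wild-type against mutant within each construct. Without that term limma called 0 catalytic clusters, with 320 at an unadjusted p under 0.05.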

Other observations

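Both tests on ZNF genes, their stricter definition and the comparison between arrays other than the control clone were chosen after the result was seen, as were the clone by construct values as separate settings; the tests on neighbouring genes and on opposing changes were written before it. Among genes named ZNF or ZFP with at least 2 others among the 5 nearest named genes on each side, 231 in all, the median knockdown difference was 0.15 (95% bootstrap interval over genes 0.095 to 0.20). In shTET1#1 it was 0.26, with 34 genes at least 2-fold higher and 0 lower, and in the array labelled shTET1#2 it was 0.046, with 12 higher and 0 lower. Requiring 3 others left 199 genes with a median of 0.18. The same 231 genes had medians of 0.086 and 0.10 for wild-type minus mutant in CD and FL, where the other 140 ZNF genes had 0.037 and 0.039. Their medians were 0.073 and 0.155 for mutant CD and FL minus vector, and 0.12 and 0.096 for FL minus CD in the wild-type and mutant pairs.

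A candidate explanation for the ZNF pattern is that the control clone alone stands apart. The vector array lay 0.201 above the control clone at the median (interval 0.10 to 0.27), more than 0.5 times the knockdown difference by 0.049 to 0.19. These intervals cover genes and not arrays, both differences share the 1 control array, and the median between shTET1#1 and the array labelled shTET1#2, where the control clone has no part, was 0.292, so a deviation of the control clone and differences between single arrays cannot be told apart. The other 140 ZNF genes had -0.085 in the array labelled shTET1#2 and 0.039 in the vector array, both minus the control clone. Low expression of these mRNAs is argued against only in that random lists matched on mean level had a median of -0.0071, without such a shift. The ZNF median lay at percentile 100 of those lists. That rank is no test, since the ZNF genes were taken up after their shift in the same values was seen. Random lists also do not keep any correlation among neighbouring genes. An effect of TET1 on these genes stays open too.

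Neighbouring genes differed together in the shRNA clones. With ZNF genes left out, a gene's difference between the 2 clones with shRNA against TET1 correlated at 0.259 with the mean of its 10 nearest genes over 10426 genes, against at most 0.033 in 100 shuffled orders and 0.103 for TET1-CD against mTET1-CD. The values were 0.30 and 0.23 for the clones against the control clone. Against the vector they were 0.179 for shTET1#1 and 0.102 for the array labelled shTET1#2, and vector minus control clone gave 0.129. The array labelled shTET1#2 against the vector was thus not above the 0.103 of the CD pair, and the control clone may add to the higher values. Neighbours that differ together are what gene copy number or other regional differences between clones may produce, and a regional response to TET1 was not tested. In the highest run of 20 neighbours, from SCML1 to APOO and including MAP7D2, medians were 1.08 and 0.51 in the clones and 0.50 for vector minus control clone. In the lowest run, from HDAC8 to APOOL, they were -0.66 and -0.17 in the clones and -0.21 for vector minus control clone. Both runs were picked as the extremes of the same knockdown values, and no runs in shuffled orders were set beside them.

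Knockdown and catalytic differences opposed each other across transcript clusters at r = -0.121. A response to TET1 activity shared by both clones and both constructs required each of the 4 pairs to lie below -0.05. The highest was 0.0629, so that prediction was not met. The test cannot exclude such a response, since the array labelled shTET1#2 had little or no lower TET1 signal. The wild-type minus mutant differences in CD and FL also correlated with each other at only 0.0042. A trend of the array values with expression level is argued against for the pooled relation, since removing it there left r = -0.118. The array labelled shTET1#2 with FL carried most of the relation, at -0.246. The trend was not removed from that pair alone, and what sets those arrays apart stays open.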
